A study of Mus musculus with 16 samples.

How the data were processed

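RNA had been sequenced from 16 bulk lung tumors of mice, 8 labelled sgControl RPP and 8 labelled sgKdm5a RPP. Per the labels' protocols, adenovirus carrying Cre and sgRNAs was given through the trachea to mice with a Cre-inducible Cas9 transgene, and tumors were collected at the end of the study. RNA was column-purified, and libraries were made with a stranded total RNA protocol, per the labels. RPP is taken here, from knowledge of the model and not from the labels, as sgRNAs against Rb1, Trp53 and Rbl2. Each column of the table carried its own number, which the source names give as that of a lung tumor. It was taken here as the number of a mouse, which the headers do not state, so each library was treated as 1 animal. Mention of mice by number below rests on this reading.

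The deposited values were read as FPKM (fragments per kilobase of transcript, scaled to library size), a unit inferred from the values although the sheet was named for counts. They were not whole numbers. Multiplied by the longest GENCODE vM21 transcript of each symbol (22633 of 24043 symbols matched, 94.1%), they summed to 1.09 to 1.19 times the total that FPKM imply in 15 libraries and to 0.368 times it in the library of sgControl RPP tumor 1. The submitters' processing notes name STAR 2.5.1b, Cufflinks 2.2.1 and genome build mm9, without giving the role of each. The gene annotation and any filter are not given in the sources used here. Total read numbers cannot be recovered from these values, so the depth of each library is unknown and no counting interval is given. Precision was judged from the spread between tumors, and the test across all genes was limma, not a count model. The reference held here is of another build than mm9, so no coordinates are given. A gene table of assembly GRCm38.p6 was used only for gene names and for which genes neighbour each other.

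The table held 24043 entries. Of these, 27 had names turned into dates by spreadsheet software and were left out, since the gene behind such a name could not be assigned. Columns of other samples numbered 0. No pair of libraries among the 120 possible was identical. Genes with at least 1 FPKM in at least 8 of the 16 libraries were tested, which left 13123 of 24016. Values were transformed to log2(FPKM + 1), with a pseudocount of 1. A log2 difference on this scale understates the change of genes with low values. The median log2 difference of all tested genes was 0.21, and it was 0.002 after each library was scaled to a common median, so list results are given relative to all tested genes.

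The groups were compared with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend and robust variance, 14 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals are 95% intervals of that model. Kdm5a was also compared by a two-sided exact permutation test over all 12870 assignments of 8 and 8 tumors. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 of 34 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The estimated correlations were 0.14 to 0.95, far above the preset, so p-values with the preset can be too small. Fry tests a list against no change, whereas camera tests it against the other genes, so their results answer different questions. Counts of list members that passed are given over all genes and adjusted over the list alone. The adjustment over the list alone does not allow for the number of lists, so some such calls can arise by chance.

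The design, the 34 lists, the rule for naming genes and the alternative settings were fixed before the data were examined. The rule names the 4 engineered loci. In each direction it names the 10 genes of largest change past the threshold with a mean of at least 1 FPKM, or, where fewer than 5 passed, those that passed and then the genes of smallest p up to 5. For each list it names up to 4 members past the threshold, or the 2 of smallest p where none passed. Neurod1, Chga, Notch2, Hes1, Rest, Yap1, Myc and Mycl are always named. Not every gene that the rule names is reported here. Any other gene named was chosen after its values were seen.

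The fit was tested on simulated values for the same 13123 genes, drawn with each gene's own mean and SD, with 200 genes changed in each of 10 runs. For this comparison it recovered 26.0% of genes changed by 1 on the log2 scale and 87.8% of those changed by 2, and 5.64% of its calls were false. A list of 20 genes shifted by 1 was called in 10 of 10 runs, and an unchanged list of 20 in 0. The simulated genes were independent of each other, unlike genes in tumors.

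The alternatives were quantile normalization, median scaling, no filter on low values, a pseudocount of 0.1, sample weights (arrayWeights), the tumor number 1 to 8 as a block, the series of the mouse numbers (190 to 238 or 839 to 893) as a covariate, the mice numbered 190 to 238 alone, the mean levels of 4 tissue lists (macrophages, T and NK cells, endothelium and alveolar type 2) as covariates, and leaving out each tumor in turn. Median scaling together with leaving out sgControl RPP tumor 1 was added after the values had been seen. Results of those 4 lists are not used in the setting where they are themselves covariates. Their mean levels were taken without scaling, so they also carry the overall level of a library, which was low in sgControl RPP tumor 1. The setting is therefore not an adjustment for tissue content alone. For a list, a change of direction between alternatives was counted only where the list passed the threshold in one of both. In addition, 100 of the 6435 possible splits of the 16 tumors into 2 groups of 8, the real one included, were fitted in the same way. Figures were drawn with matplotlib.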

Results

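Bulk RNA was measured in 16 mouse small cell lung tumors, a neuroendocrine lung cancer that in this model arises after Cas9 editing of Rb1, Trp53 and Rbl2. Of these, 8 carried the label sgControl RPP and 8 the label sgKdm5a RPP, whose virus held an added sgRNA against Kdm5a, the gene of a histone H3 lysine 4 demethylase. The study asked how loss of Kdm5a alters gene expression in such tumors, and known work links the enzyme to repression of NOTCH signaling and to the neuroendocrine state. Values were FPKM with unknown read depth. Group means of FPKM are unscaled and include sgControl RPP tumor 1. Its median of tested genes was 2.38 FPKM, against 10.0 to 12.3 FPKM in the other tumors. This lowers the sgControl-labelled mean of most genes, whereas list positions are relative to all tested genes. A named gene can therefore have a higher mean while its list lies lower. Because Kdm5a RNA ran against the labels, as described next, the groups are called the sgKdm5a-labelled and sgControl-labelled tumors throughout. All differences are sgKdm5a-labelled minus sgControl-labelled, and each direction rests on those labels.

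Kdm5a RNA was higher, not lower, in the tumors labelled as edited at Kdm5a. It averaged 13.0 ± 3.10 FPKM (SD, n = 8) in the sgKdm5a-labelled tumors and 6.83 ± 1.64 FPKM (SD, n = 8) in the sgControl-labelled tumors. The 8 sgKdm5a-labelled tumors held 8.16 to 17.3 FPKM, each above the highest sgControl-labelled tumor at 8.06 FPKM. The log2 difference was 0.84 (fold 1.79), with a two-sided exact permutation p of 0.000155, the smallest that 12870 assignments can give. Over all tested genes its adjusted p was 0.852 (limma, Benjamini-Hochberg). Indels from Cas9 need not lower the RNA of a gene, and the edited sequence itself was not analysed here, so these values do not show which tumors were edited. Among mice numbered 190 to 238 (4 sgKdm5a-labelled, 7 sgControl-labelled) the log2 difference was 1.01 (exact permutation p = 0.00303), while the series 839 to 893 held 1 sgControl-labelled tumor and was not tested alone. Without sgControl RPP tumor 1, in which Kdm5a was 3.28 FPKM, the difference was 0.72 (exact permutation p = 0.000311). Divided by each library's median of tested genes, Kdm5a differed by 0.67 on the log2 scale (exact permutation p = 0.00870), and the full separation was lost: sgControl RPP tumor 1 stood at 1.38 times its median, above 6 of the 8 sgKdm5a-labelled tumors (0.727 to 1.73). In addition, sgControl RPP tumor 3, at 0.730, stood just above sgKdm5a RPP tumor 5, at 0.727.

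Like Kdm5a, the other engineered loci did not pass the test over all genes. Rb1, the retinoblastoma tumor suppressor, averaged 7.73 ± 2.12 FPKM in the sgKdm5a-labelled and 11.2 ± 4.18 FPKM in the sgControl-labelled tumors (SD, n = 8 each). Its relative Rbl2 averaged 6.65 ± 2.45 and 9.61 ± 3.19 FPKM in the same order. Their log2 differences were -0.45 and -0.47 (adjusted p = 0.852 for both, limma). Relative to the median of all tested genes they were -0.66 and -0.68, against 0.63 for Kdm5a. Trp53 averaged 14.1 ± 9.93 and 17.8 ± 17.97 FPKM. It lay between 28.9 and 53.4 FPKM in 4 tumors, a pair in each group, and at 14.4 FPKM or less in the other 12. In the engineered loci list, 1 of 4 members, Kdm5a, was higher when adjusted over the list alone (adjusted p = 0.00662, limma), against 0 over all genes.

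**Figure D1:**
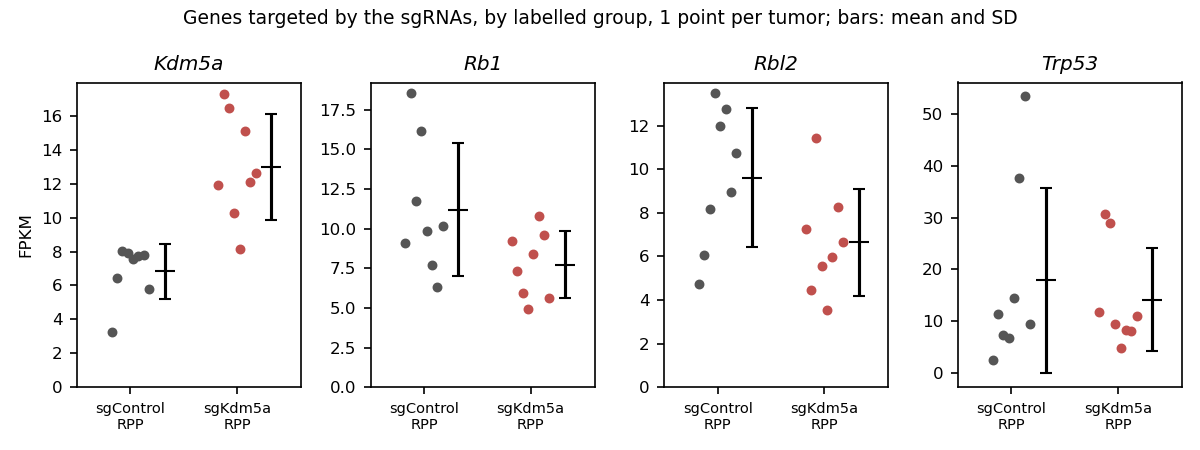
FPKM of the 4 genes targeted by the sgRNAs (vertical axis, starting at 0 or below) in each tumor (points) of the 2 labelled groups (horizontal axis), with the mean and SD of 8 tumors as bars. The 8 sgKdm5a-labelled tumors lie between 8.16 and 17.3 FPKM for Kdm5a, all above the sgControl-labelled tumors, while the groups overlap for Rb1, Rbl2 and Trp53.

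Of 13123 tested genes, 1 rose in the sgKdm5a-labelled tumors and 0 fell. Nell1, which encodes a secreted protein known from bone formation, rose from 0.754 ± 0.528 to 11.3 ± 11.5 FPKM (SD, n = 8 each), a log2 difference of 2.43 with a standard error of 0.40 (adjusted p = 0.0483, limma). It was above every sgControl-labelled tumor in 7 of 8 sgKdm5a-labelled tumors, with 1.20 FPKM in the remaining one, sgKdm5a RPP tumor 1, and 38.0 FPKM in sgKdm5a RPP tumor 2. The call was lost on leaving out any one of 14 of the 16 tumors and in most other settings, although Nell1 stayed higher in all 25 settings in which it was tested (adjusted p 0.00103 to 0.369, limma). At an unadjusted p under 0.05, 488 genes were higher and 92 lower in limma, 580 in all against 656 that chance would give. After median scaling 621 were higher and 682 lower, and without sgControl RPP tumor 1 these were 487 and 672.

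The next genes by p had an adjusted p of 0.852 (limma). Higher in the sgKdm5a-labelled tumors were Cntnap5b, a contactin-associated cell surface protein (6.69 ± 3.78 against 1.55 ± 0.909 FPKM), and Nmnat2, an NAD synthesis enzyme of neurons (4.41 ± 3.66 against 0.903 ± 0.756 FPKM). The sorting nexin Snx11 (20.1 ± 5.52 against 8.03 ± 3.37 FPKM) and the cation channel gene Trpc4 (3.98 ± 2.76 against 0.672 ± 0.699 FPKM) completed this set. Lower were Pipox, an enzyme of pipecolic acid breakdown (2.802 ± 3.26 against 8.04 ± 3.91 FPKM), and Hamp, the gene of the iron hormone hepcidin (0.837 ± 1.07 against 4.74 ± 4.07 FPKM). The neuronal intermediate filament gene Prph (15.5 ± 10.7 against 38.8 ± 17.4 FPKM) and Dlk2 (2.21 ± 1.91 against 6.996 ± 5.19 FPKM) were also on this side. Rps27, a ribosomal protein gene, had the largest of these differences, with 39.4 ± 74.8 against 808 ± 500 FPKM (log2 difference -4.76). Rps27 has a near-identical copy, Rps27rt, and reads may be split between both, so its value is uncertain. Their summed FPKM was 1649 ± 262 in the sgKdm5a-labelled and 1537 ± 412 in the sgControl-labelled tumors (SD, n = 8 each), a log2 difference of 0.15.

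**Figure D2:**
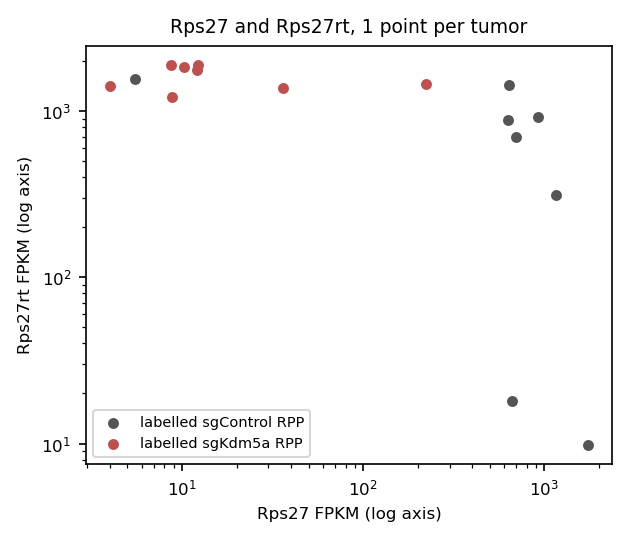
FPKM of Rps27 (horizontal log axis) against its near-identical copy Rps27rt (vertical log axis), 1 point per tumor, colored by labelled group. Rps27 made up more than 25% of the sum of both genes in 7 of 8 sgControl-labelled and 0 of 8 sgKdm5a-labelled tumors.

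Neuroendocrine genes, which mark the cell state of this cancer, stood higher than other genes in the sgKdm5a-labelled tumors: 18 of 25 tested members lay above the median difference of all genes (adjusted p = 0.00650, limma camera with the preset correlation). That call was lost with an estimated correlation (adjusted p = 0.819) and without sgControl RPP tumor 1 or 5 (adjusted p = 0.0519 and 0.0593), with sample weights (0.0584) and in the mice numbered 190 to 238 alone (0.0863). The list median lay 0.29 above that of all genes, 0.26 without sgControl RPP tumor 1, and 0.26 with median scaling, where the list passed (adjusted p = 0.0105). With the tissue lists as covariates, which also carry the overall level of each library, the list median lay 0.08 above and the list mean 0.27 above. The list still passed in that setting. Chga, the gene of the granule protein chromogranin A, averaged 968 ± 554 against 299 ± 185 FPKM (SD, n = 8 each) and lay above the sgControl-labelled median in 8 of 8 tumors. The secretory granule gene Scg5 averaged 224 ± 112 against 82.1 ± 37.1 FPKM. Both passed, higher, when adjusted over the list alone, which does not allow for the number of lists. The count was 2 members there and 0 over all genes. The mean log2 level of the list was 3.83 in sgControl RPP tumor 1, against group means of 6.07 ± 0.96 (sgControl-labelled) and 6.76 ± 0.25 (sgKdm5a-labelled, SD, n = 8 each).

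Subtype factors of small cell lung cancer did not pass as a list (4 of 5 tested members above the all-gene median, camera adjusted p = 0.545). Myc averaged 7.94 ± 7.91 against 3.74 ± 1.72 FPKM, with 27.1 FPKM in sgKdm5a RPP tumor 8, and Mycl averaged 76.8 ± 72.0 against 86.4 ± 97.8 FPKM. The log2 difference of Mycl, 0.12 although its mean FPKM was lower, changed sign under both other scalings. Neurod1, below the filter, averaged 5.32 ± 7.59 against 1.30 ± 2.00 FPKM and was not tested. Tuft cell genes had 2 tested members, Avil (5.003 ± 6.11 against 2.24 ± 1.88 FPKM) and Dclk1 (1.86 ± 1.11 against 1.63 ± 1.39 FPKM), too few for a list test.

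NOTCH pathway genes did not separate from other genes, with 9 of 18 tested members above the all-gene median (camera adjusted p = 0.489). The receptor gene Notch2 averaged 1.76 ± 0.763 against 2.08 ± 1.45 FPKM, a log2 difference of -0.07 with a standard error of 0.27. The NOTCH target genes Hes1 (12.5 ± 4.97 against 9.73 ± 6.78 FPKM), Hey1 (15.2 ± 4.42 against 9.30 ± 3.45 FPKM) and Heyl (4.14 ± 2.82 against 2.60 ± 1.01 FPKM) did not pass. Rest, a repressor of neuronal genes, was below the filter at 1.19 ± 0.868 against 0.391 ± 0.412 FPKM. Genes of YAP signaling and the non-neuroendocrine state lay above the all-gene median in 13 of 13 tested members without passing (camera adjusted p = 0.101), although the list passed, higher, in 7 of 28 other settings. Among them were Yap1 (3.21 ± 1.20 against 2.86 ± 3.62 FPKM) and Wwtr1 (5.31 ± 2.70 against 3.24 ± 3.29 FPKM). For Yap1, 1 sgControl-labelled tumor at 11.5 FPKM carried its group mean, and the medians were 3.16 against 1.38 FPKM (log2 difference 0.41). In the epithelial-mesenchymal list, 7 of 10 members lay above (camera adjusted p = 0.324), including Fn1 (60.3 ± 48.3 against 24.8 ± 10.7 FPKM) and Mmp14 (26.4 ± 17.1 against 14.3 ± 7.56 FPKM).

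Mitosis genes stood lower than other genes in the sgKdm5a-labelled tumors, with 18 of 20 tested members below the all-gene median and a list median 0.31 under it on the log2 scale (camera adjusted p = 0.000233, and 0.819 with an estimated correlation). In mice 190 to 238 alone the list median lay 0.51 under that of all genes. The proliferation marker Mki67 averaged 66.1 ± 15.4 against 98.1 ± 27.1 FPKM (SD, n = 8 each), with 0 of 8 sgKdm5a-labelled tumors above the sgControl-labelled median. The mitotic kinase gene Aurka averaged 47.1 ± 9.49 against 34.8 ± 17.8 FPKM, the opposite way. With 4 tissue lists (macrophages, T and NK cells, endothelium and alveolar type 2) as covariates, the mitosis list median lay 0.16 under that of all genes (camera adjusted p = 0.0536). These covariates also carry the overall level of each library. E2F and S phase genes lay below the all-gene median in 14 of 20 members (camera adjusted p = 0.296), with Mcm5 at 104 ± 29.5 against 71.8 ± 33.4 FPKM and Pola1 at 22.3 ± 9.49 against 29.1 ± 11.6 FPKM. Replication-dependent histone genes, whose RNAs lack poly(A) tails, were below in 5 of 5 tested members (camera adjusted p = 0.000242, and 0.819 with an estimated correlation). This call was lost without sgControl RPP tumor 1 (adjusted p = 0.372), with median scaling (0.0747), quantile normalization (0.0819) and sample weights (0.230), and with the tissue lists as covariates the direction turned (0.202, higher). The list median lay 0.91 below that of all genes, 0.94 with median scaling and 0.39 without sgControl RPP tumor 1. Hist1h4d averaged 1.46 ± 0.725 against 3.31 ± 2.77 FPKM and Hist1h2bc 41.6 ± 32.2 against 67.4 ± 45.9 FPKM.

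Targets of p53 lay above the all-gene median in 12 of 15 members without passing as a list (camera adjusted p = 0.296). Trp53inp1, a p53-induced stress gene, was higher when adjusted over the list alone (adjusted p = 0.0369, limma, 1 member there and 0 over all genes), with 37.0 ± 20.5 against 17.0 ± 6.30 FPKM. Mdm2 averaged 32.7 ± 5.75 against 24.6 ± 7.64 FPKM. The related H3K4 demethylase genes did not pass (camera adjusted p = 0.744). Kdm5b averaged 6.76 ± 1.65 against 4.88 ± 3.08 FPKM and Kdm5c 13.6 ± 4.11 against 10.2 ± 3.99 FPKM.

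Macrophage, fibroblast and endothelial genes each stood higher than other genes in the sgKdm5a-labelled tumors. Of the tested members, 13 of 16, 11 of 12 and 12 of 13 lay above the all-gene median (camera adjusted p = 0.00650, 0.00650 and 0.00679, and 0.819 for each with an estimated correlation). The lysozyme gene Lyz2 averaged 512 ± 344 against 413 ± 676 FPKM, and the macrophage receptor gene Trem2 averaged 7.96 ± 3.66 against 4.54 ± 1.62 FPKM. For Lyz2, 1 sgControl-labelled tumor at 2047 FPKM carried its group mean, and the medians were 498 against 153 FPKM (log2 difference 1.32). In fibroblasts the matrix gene Dcn averaged 89.9 ± 73.5 against 43.8 ± 74.7 FPKM and the receptor gene Pdgfra 4.38 ± 3.15 against 2.07 ± 2.204 FPKM. Dcn reached 226 FPKM in 1 sgControl-labelled tumor, and its medians were 80.1 against 19.0 FPKM (log2 difference 1.62). In endothelium Esam averaged 14.9 ± 5.66 against 10.1 ± 8.61 FPKM and Tie1 6.23 ± 3.09 against 3.67 ± 2.74 FPKM. All 3 calls held without sgControl RPP tumor 1 (adjusted p = 0.00759, 0.0166 and 0.00759). With the tissue lists as covariates, of which fibroblasts are not one, the fibroblast list median moved from 0.81 to 0.24 above that of all genes (camera adjusted p = 0.212). These covariates also carry the overall level of each library, so this is not an adjustment for tissue content alone. The fibroblast median lay 1.28 above with the number series as a covariate and 2.02 above in mice 190 to 238 alone. The fibroblast call was lost without sgKdm5a RPP tumor 7 or 8 (adjusted p = 0.108 and 0.0662, list medians 0.47 and 0.49 above), and the endothelial call without sgControl RPP tumor 2, 4 or 8 or sgKdm5a RPP tumor 8 (adjusted p = 0.0588, 0.0556, 0.0926 and 0.0613). The endothelial list median lay 0.44 above that of all genes with all tumors, and 0.40, 0.34, 0.39 and 0.28 above without these 4 in turn. It lay 0.88 above in mice 190 to 238 alone and 0.74 above with sample weights. Ciliated cell genes stood lower in 7 of 7 tested members (camera adjusted p = 0.0273), among them Mcidas (1.13 ± 0.910 against 3.31 ± 2.97 FPKM) and Rsph1 (17.4 ± 6.76 against 21.3 ± 11.4 FPKM). This call was lost with an estimated correlation (adjusted p = 0.819), without sgControl RPP tumor 1 or 5 (adjusted p = 0.497 and 0.593) and without sgKdm5a RPP tumor 5 or 7 (adjusted p = 0.1001 and 0.0595), and with quantile normalization (0.197), median scaling (0.206), no filter on low values (0.115) and tissue lists as covariates (0.970). Its direction turned with sample weights (adjusted p = 0.753) and in mice 190 to 238 alone (adjusted p = 0.590). The list median lay 0.31 below that of all genes, 0.36 with median scaling and 0.07 without sgControl RPP tumor 1. Without sgControl RPP tumor 5 it lay 0.05 above, although the test still pointed lower.

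Other cell types of lung and blood did not pass as lists with the settings used here. In 28 other settings B and plasma cell genes passed in 6, club cell genes in 3 and, of 27 settings in which they were not themselves a covariate, alveolar type 2 genes in 4, all higher, and erythroid genes passed in 6, lower. B and plasma cell genes lay above the all-gene median in 5 of 5 members (camera adjusted p = 0.104), with Cd79a at 8.91 ± 6.03 against 4.27 ± 6.52 FPKM and Mzb1 at 10.8 ± 17.2 against 3.69 ± 4.80 FPKM. T and NK cell genes did so in 3 of 4 (adjusted p = 0.744), with Gzma at 2.68 ± 2.45 against 0.984 ± 0.829 FPKM and Lck at 5.43 ± 1.25 against 4.49 ± 2.28 FPKM. Neutrophil genes did so in 1 of 4 (adjusted p = 0.240), with S100a9 at 3.47 ± 1.89 against 16.4 ± 37.3 FPKM and Il1b at 2.52 ± 2.49 against 2.53 ± 1.06 FPKM. The neutrophil direction rested on sgControl RPP tumor 1 (S100a9 108 FPKM): without it the list median moved from 0.26 below to 0.26 above that of all genes, and the log2 difference of S100a9 from -0.42 to 0.20. Alveolar type 2 cells, the surfactant producers, had 10 of 12 members above (adjusted p = 0.296), including Lyz1 (32.6 ± 27.7 against 41.0 ± 93.5 FPKM) and Etv5 (10.8 ± 9.53 against 6.04 ± 5.97 FPKM). For Lyz1, and below for Cav1 and Tnnt2, sgControl RPP tumor 5 carried the sgControl-labelled mean (272, 177 and 24.1 FPKM), so the log2 differences were 1.23, 0.78 and 0.49 although the mean FPKM was lower. Alveolar type 1 genes had 4 of 10 above (adjusted p = 0.397), with Cav1 at 22.8 ± 14.8 against 29.5 ± 59.8 FPKM and Rtkn2 at 4.40 ± 1.49 against 6.90 ± 2.96 FPKM. Club cell genes had 6 of 8 above (adjusted p = 0.744), with Cldn10 at 6.35 ± 5.40 against 3.95 ± 5.20 FPKM and Hp at 90.7 ± 69.5 against 68.2 ± 131 FPKM. Erythroid genes lay below in 4 of 4 (adjusted p = 0.101), with Hba-a1 at 314 ± 184 against 416 ± 262 FPKM and Hbb-b1 at 343 ± 222 against 488 ± 358 FPKM. Heart muscle and mesothelium lists had adjusted p of 0.349 and 0.522. Their named members were Tnni3 (1.68 ± 1.52 against 4.59 ± 7.32 FPKM), Tnnt2 (3.36 ± 4.28 against 3.55 ± 8.32 FPKM), Krt19 (51.2 ± 49.7 against 32.9 ± 33.6 FPKM) and Msln (2.805 ± 2.02 against 7.51 ± 13.6 FPKM).

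Interferon response genes, which signal antiviral and immune activation, lay below the all-gene median in 18 of 24 members without passing (camera adjusted p = 0.120), and passed, lower, in 6 of 28 other settings. Bst2 averaged 46.6 ± 28.6 against 31.2 ± 21.9 FPKM and Irf1 30.9 ± 11.3 against 24.4 ± 11.3 FPKM. Genes of class I antigen presentation had an adjusted p of 0.732, with H2-D1 at 705 ± 239 against 569 ± 315 FPKM and Tapbp at 57.2 ± 30.2 against 38.7 ± 19.4 FPKM. Genes of class II had an adjusted p of 0.770, with H2-Ab1 at 67.3 ± 40.1 against 71.0 ± 71.1 FPKM and H2-DMa at 6.33 ± 2.49 against 5.97 ± 5.45 FPKM. The log2 difference of H2-Ab1 was 0.37 although its mean FPKM was lower, with 241 FPKM in sgControl RPP tumor 5. Immediate early and stress genes, which respond to tissue handling, had 2 of 11 members above (adjusted p = 0.0572, and under 0.05, lower, in 11 of 28 other settings), with Fos at 7.68 ± 3.40 against 26.4 ± 52.6 FPKM and Junb at 40.8 ± 28.3 against 27.5 ± 20.98 FPKM. Hypoxia and glycolysis genes had 7 of 14 above (adjusted p = 0.744), with Egln3 at 47.8 ± 18.1 against 33.0 ± 22.8 FPKM and Adm at 8.08 ± 7.53 against 4.05 ± 3.09 FPKM. Oxidative phosphorylation genes had 5 of 20 above (adjusted p = 0.744), with Atp5g1 at 143 ± 32.1 against 117 ± 43.0 FPKM and Ndufb8 at 234 ± 66.4 against 191 ± 85.9 FPKM. In sgControl RPP tumor 1, Atp5g1 stood at 19.6 FPKM (others of its group 105 to 157) and Ndufb8 at 31.4 FPKM (others 139 to 293). Irf1, Rpl19 and Tef also stood lowest of their group there, which lowers these sgControl-labelled means. Ribosomal protein genes had 4 of 20 above (adjusted p = 0.101). They passed, lower than other genes, in 10 of 28 other settings, among them median scaling (adjusted p = 0.0105) and without sgControl RPP tumor 1 (adjusted p = 0.0129). Rpl19 averaged 1194 ± 259 against 995 ± 384 FPKM and Rps24 702 ± 153 against 946 ± 362 FPKM. Circadian clock output genes had 3 of 12 above (adjusted p = 0.296), with Nr1d1 at 24.96 ± 8.29 against 20.3 ± 8.17 FPKM and Tef at 41.0 ± 13.96 against 36.2 ± 15.4 FPKM. Of the sex-linked genes only Xist was tested, too few for a list (29.1 ± 22.0 against 26.7 ± 24.1 FPKM). Xist was under 1 FPKM and Ddx3y over 1 FPKM in 2 of 8 tumors of each group.

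**Figure D3:**
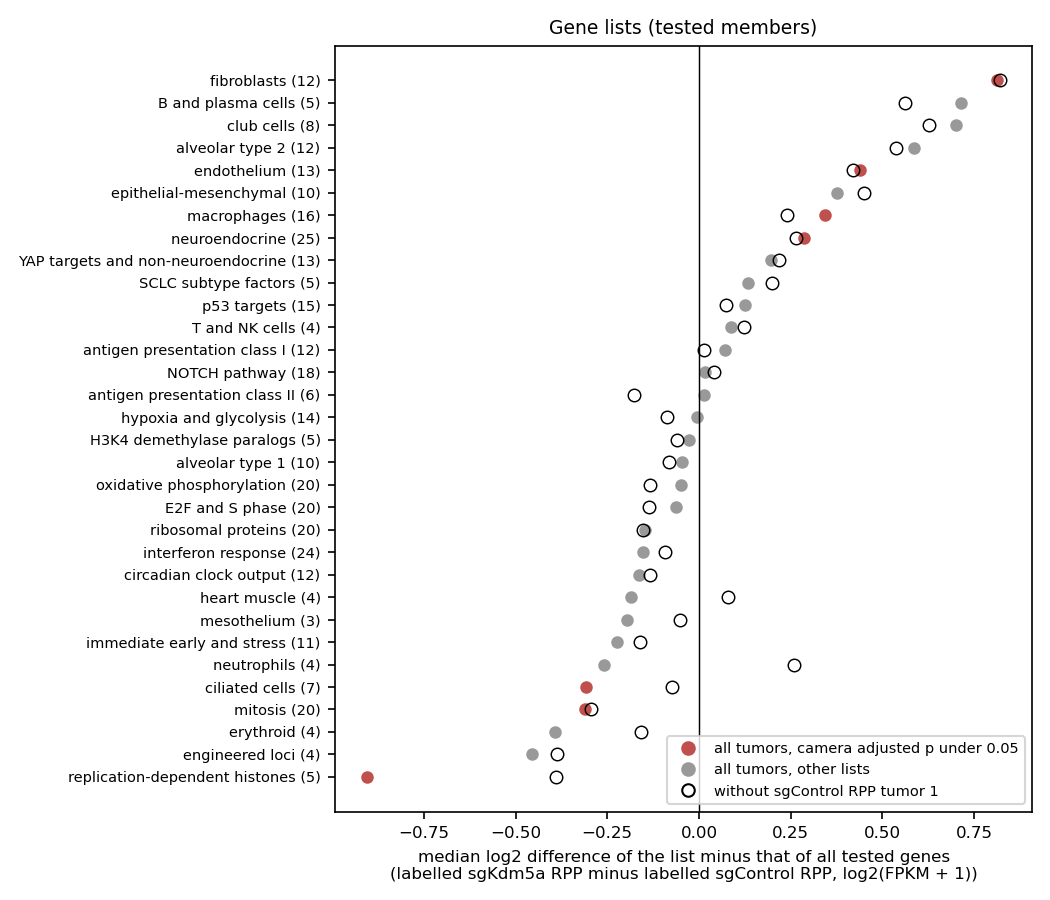
Median log2 difference (sgKdm5a-labelled minus sgControl-labelled) of the tested members of 32 gene lists, minus the median of all tested genes (horizontal axis), with the number of tested members in brackets. Filled points use all 16 tumors and open points leave out sgControl RPP tumor 1; fibroblasts lie at 0.81 and 0.82, replication-dependent histones at -0.91 and -0.39, and neutrophils at -0.26 and 0.26.

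In all, 7 of 32 lists passed with the preset correlation, 4 higher and 3 lower, against 0 with an estimated correlation (estimates 0.14 to 0.95) and 0 with fry (smallest adjusted p = 0.819 and 0.673). When the tumors were regrouped without regard to the labels, 87 of 100 groupings, the labelled one included, gave at least 7 lists. The median of the others was 11, so the calls with the preset correlation do not set the labelled groups apart from chance. Without sgControl RPP tumor 1, 5 lists passed, 4 of them shared with the 7. Adjusted over the list alone, no member passed in any list other than the engineered loci, neuroendocrine and p53 target lists. That adjustment does not allow for the number of lists, and over all genes no member of any list passed. The list median, mean and test differed in sign for class I and class II antigen presentation (median 0.07 and 0.01 above all genes, mean 0.01 and 0.03 above, test lower). They also differed for the H3K4 demethylase paralogs (median -0.03, mean 0.03, test higher) and for hypoxia and glycolysis (median -0.005, mean 0.07, test higher).

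The library of sgControl RPP tumor 1 stood apart. The microRNA locus Mir6236 made up 88.9% of its summed FPKM, against 5.76% to 15.2% in the other 15 libraries, and the median of tested genes was 2.38 FPKM against 10.0 to 12.3. It had 9921 genes at 1 FPKM or more, against 12573 to 14187. A share of summed FPKM is not a share of reads, since FPKM are divided by transcript length. Pearson correlations between libraries across genes were 0.75 to 0.95, with medians of 0.88 within the sgControl-labelled group, 0.90 within the sgKdm5a-labelled group and 0.89 between groups.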

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

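The 3 patterns weighed below were picked after the values were seen, and of their tests only the length trend had its prediction written beforehand; the others were chosen after the result was seen. A single tumor far from the other 7 of its group (Dixon's test, on the log2 scale for FPKM) was found in 34 of 174 tests, against 8.7 that chance, about 1 in 20, would give. Of these, 24 were in sgControl RPP tumor 1, whose values were low for most genes, so they are not independent of each other. The flags in all other tumors together were close in number to the 8.7 that chance would give.

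Kdm5a RNA was higher in the tumors labelled sgKdm5a RPP, against the direction that loss of the gene might bring, although indels need not lower RNA. Low values of sgControl RPP tumor 1 were argued against, since without it and with median scaling the 95% interval of the log2 difference began at 0.397. A gain of the chromosome region was argued against by 10 flanking genes, whose median lay -0.062 from that of all genes, against 0.63 for Kdm5a. The number series of the mice was argued against by the exact permutation p of 0.00303 within mice 190 to 238. A whole exchange of both groups' labels was not tested, nor was any biological explanation, such as a response of the edited gene.

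Rps27 was lower in the sgKdm5a-labelled tumors, and reads shared with its copy Rps27rt fit this, since the summed FPKM of both differed by only 0.145 on the log2 scale. Rps27 made up 0.351% to 99.4% of the sum in the sgControl-labelled and 0.281% to 13.2% in the sgKdm5a-labelled tumors. A strain variant that moves reads from one copy to the other would look the same and was not tested, and no biological explanation was tested.

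The library of sgControl RPP tumor 1 had 88.9% of its summed FPKM in Mir6236 (5.76% to 12.7% in the rest of its group), a sum of 112996 FPKM without that gene (439150 to 494434), 9921 genes at 1 FPKM or more (12583 to 14187) and a median of 2.38 FPKM (11.03 to 12.03). Dilution by Mir6236 alone was predicted to leave a spread within that of the rest of its group after median scaling. The genes of this library deviated with an SD of 0.932, against 0.441 to 0.800 in the rest of its group. The spread cannot decide the question, since fewer fragments for the other genes would themselves raise it and depth was unknown. Multiplied by transcript length, this library's FPKM summed to 0.368 times the total that FPKM imply, against 1.09 to 1.19 in the other 15. Fragments moved to Mir6236 alone would leave that sum unchanged, so it argues against this explanation if Mir6236 was among the matched symbols. Whether it was is not known here. A trend with transcript length was argued against by a Spearman rho of 0.040, inside the -0.236 to 0.226 of the other 15 libraries. More RNA without poly(A) tails fit. The histone list (10 genes, unfiltered) lay 3.63 above the other tumors on the log2 scale after median scaling. For each of the 15 others the value was -0.776 to 1.20. The excess was not particular to this list, so the test does not single out that explanation. The neutrophil list lay 2.49 above (at most 0.854 in the 15) and the erythroid list 1.68 above (at most 1.02). No biological explanation was tested.

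In the same tumor, whose median was 4.88 times lower than that of the other tumors, most genes named here had low FPKM. Over the library median, 11 of these 20 genes lay below the rest of the group, 6 within its range and 3 (Kdm5a, Mdm2, S100a9) above it, Kdm5a at 1.38 against 0.481 to 0.730. In FPKM, the neuroendocrine gene Scg5 stood at 9.82 (others of its group 59.6 to 129). Engineered and chromatin genes were Kdm5a (3.28, others 5.77 to 8.06) and Kdm5c (1.93, others 6.92 to 14.3). NOTCH targets were Hey1 (2.27, others 6.60 to 12.7) and Heyl (0.410, others 2.16 to 3.72). Matrix and p53 genes were Fn1 (5.96, others 17.0 to 38.4), Mmp14 (1.24, others 9.61 to 28.1) and Mdm2 (6.91, others 23.1 to 30.5). Cell cycle genes were Aurka (3.48, others 19.4 to 58.0) and Mcm5 (8.19, others 41.7 to 106). Immune genes were H2-Ab1 (2.40, others 49.7 to 241), Tapbp (2.39, others 28.4 to 62.2), Irf1 (4.06, others 19.2 to 41.9) and Lck (0.594, others 3.13 to 7.62). Housekeeping and clock genes were Atp5g1 (19.6, others 105 to 157), Ndufb8 (31.4, others 139 to 293), Rpl19 (245.6, others 817 to 1608) and Tef (5.40, others 30.1 to 56.2). Snx11 stood at 0.734 (others 7.17 to 11.4), and the neutrophil gene S100a9 at 108 (others 0.716 to 6.94).

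In other tumors labelled sgControl RPP, Cav1 was 177 FPKM (others 2.47 to 21.2) and Tnnt2 24.1 FPKM (others 0.102 to 1.497), both in tumor 5. In tumor 3, Fos was 156 FPKM (others 5.05 to 11.8) and Rps27 5.50 FPKM (others 634 to 1743). In tumors labelled sgKdm5a RPP, Myc was 27.1 FPKM in tumor 8 (others 3.01 to 7.65) and Trem2 16.2 FPKM in tumor 4 (others 4.94 to 8.81). In tumor 3, Trp53inp1 was 85.1 FPKM (others 21.4 to 40.1) and S100a9 0.318 FPKM (others 2.46 to 6.23). Hp was 0.768 FPKM in tumor 7 (others 26.7 to 194), and Hist1h4d was listed at 0 in tumor 5 (others 0.890 to 2.27).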

How the results depend on the processing

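Depth was unknown for these FPKM, so limits from depth could not be set, and count models were not run because the values were not counts. Kdm5a was higher in all 26 alternative settings (log2 difference 0.55 to 1.01, adjusted p 0.0600 to 0.992, limma). For the other named genes 1952 of 2046 results kept direction and side of the threshold, and 69 in 33 genes reversed. Keeping the side says little, since every tested one but Nell1 had an adjusted p of 0.852 or more (limma). Most settings, moreover, only left out 1 tumor. Nell1 lost its call in 21 of its 25 settings. The cause of the reversals was not tested.

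The number of genes higher in the sgKdm5a-labelled tumors, 1 with the settings of the report (Nell1), was 0 with quantile normalization, median scaling, no filter on low values, a pseudocount of 0.1, mice 190 to 238 alone, tissue lists as covariates, and median scaling without sgControl RPP tumor 1. With sample weights 2 were higher (Ccdc132, Snx11) and 3 lower (Acat1, Aqp4, Pipox), against 0 lower in the report. Leaving out each tumor gave 0 to 2 higher (2, Cntnap5b and Nell1, without sgKdm5a RPP tumor 2) and 0 to 1 lower (Rps27 without sgControl RPP tumor 3). At an unadjusted p under 0.05, 488 were higher and 92 lower, against 621 and 682 with median scaling, 487 and 672 without sgControl RPP tumor 1, 1164 and 1177 with sample weights, and 71 and 1733 with tissue lists as covariates (656 in all by chance). Lists past the threshold, 7 in the report, were 0 with an estimated correlation, 0 with fry, 5 to 12 on leaving out each tumor, and 6 to 10 otherwise (of the 8 with tissue lists as covariates, 2, endothelium and alveolar type 2, are covariates themselves and are not results). Lists that did not pass in the report passed in some of 28 other settings: immediate early and stress in 11, ribosomal proteins in 10, YAP in 7, interferon, B and plasma cells and erythroid in 6 each, alveolar type 2 in 4 of 27 (not counting that with itself as a covariate), club cells in 3, neutrophils (1 in each direction) and oxidative phosphorylation in 2, and epithelial-mesenchymal, E2F, class II, alveolar type 1 and circadian in 1 each. With the tumor number as a block, 1 gene was higher and 0 lower, the Kdm5a difference was 0.84 and 8 lists passed; no sign of pairing was found, since 2 of 8 same-numbered pairs correlated above 0.1 (-0.313 to 0.356) and 2 of 16 tumors correlated best with their own number.

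Reversed log2 differences were, with quantile normalization, Dclk1 -0.012, Mycl -0.16 and Xist -0.066, and with median scaling Mycl -0.11 and Xist -0.055. With sample weights they were Mycl -1.14, S100a9 0.28, Tef -0.14, Tnni3 0.60 and Xist -0.56, and the ciliated list turned higher (adjusted p = 0.753). With the number series as a covariate it was H2-DMa -0.042. In mice 190 to 238 alone they were Msln 0.077, Notch2 0.29, S100a9 0.015 and Trp53 0.047, and the ciliated list turned higher (adjusted p = 0.590). With tissue lists as covariates they were Atp5g1 -0.20, Aurka -0.045, Bst2 -0.26, Cav1 -0.080, Dclk1 -0.18, Etv5 -0.045, H2-Ab1 -0.82, H2-D1 -0.30, H2-DMa -0.18, Hbb-b1 0.038, Hes1 -0.0011, Heyl -0.067, Irf1 -0.25, Junb -0.11, Kdm5c -0.11, Krt19 -0.17, Lck -0.19, Mcm5 -0.012, Mdm2 -0.014, Mmp14 -0.15, Mycl -0.66, Ndufb8 -0.12, Nr1d1 -0.026, Rpl19 -0.076, S100a9 0.64, Tapbp -0.44, Tef -0.32, Tnni3 0.26 and Tnnt2 -0.036, of which Etv5 and Lck belong to the covariate lists. There the histone list turned higher (adjusted p = 0.202), as did the neutrophil list (adjusted p = 0.0080). With median scaling and without sgControl RPP tumor 1 they were H2-Ab1 -0.15, Mycl -0.36, S100a9 0.21 and Tef -0.00042. On leaving out each tumor, the ranges that crossed 0 were H2-Ab1 -0.17 to 0.71, Msln -0.56 to 0.18, Mycl -0.38 to 0.50, Notch2 -0.18 to 0.076, S100a9 -0.66 to 0.20, Tef -0.019 to 0.43, Trp53 -0.32 to 0.25 and Xist -0.33 to 0.76. The cause of these reversals was not tested.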

Other observations

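The observations in this part and their tests were chosen after the values were seen, except the regrouping of tumors at its end, whose predictions were written before. Homeobox genes of the Hoxb cluster, which pattern the body axis in embryos, varied widely between tumors; they were met among the leading genes of a principal component in an exploratory look. Hoxb9 averaged 35.5 ± 34.1 FPKM in the sgKdm5a-labelled and 6.15 ± 13.8 FPKM in the sgControl-labelled tumors, Hoxb6 70.6 ± 57.8 against 17.6 ± 24.1 FPKM, and Hoxb5 62.7 ± 40.8 against 16.9 ± 16.5 FPKM (SD, n = 8 each). In sgControl RPP tumor 8, Hoxb9 was 40.3 FPKM (others of its group 0.0847 to 3.93) and Hoxb6 67.2 FPKM (others 0.441 to 40.8). Conversely, in sgKdm5a RPP tumor 2 Hoxb9 was listed at 0, Hoxb6 at 0.277 and Hoxb5 at 0.548 FPKM. Hoxb9 was 0.350 FPKM in sgKdm5a RPP tumor 5. Differences were smaller for Hoxb2 and Hoxb3 (log2 difference 0.95 and 0.84) than for Hoxb9 (2.48). The mean of the 8 tested genes from Hoxb2 to Hoxb9 differed by 1.64 on the log2 scale (exact permutation p = 0.0793), by 1.62 in mice 190 to 238 (exact permutation p = 0.215) and by 1.56 without sgControl RPP tumor 1 (exact permutation p = 0.117). Tph1, the gene of the serotonin synthesis enzyme of peripheral tissues, averaged 445 ± 694 against 20.8 ± 49.5 FPKM (log2 difference 4.32, adjusted p = 0.852, limma) and lay above the sgControl-labelled median in 7 of 8 sgKdm5a-labelled tumors. Each mean rested largely on 1 tumor, and without the highest of each group (2024 FPKM in sgKdm5a RPP tumor 8, 143 FPKM in sgControl RPP tumor 8) the means were 219.5 ± 293 and 3.33 ± 4.91 FPKM (SD, n = 7 each).

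Across 15 tumors of both groups (sgControl RPP tumor 1 left out, median scaled), some gene lists varied together. Genes of class I antigen presentation varied with interferon response genes, which share 0 members (Pearson r = 0.80, permutation p = 0.00032, adjusted over 496 pairs of lists p = 0.0144), and Spearman's rho was 0.84. Genes of YAP signaling and the non-neuroendocrine state varied against E2F and S phase genes (r = -0.91, permutation p = 0.00004, adjusted p = 0.0033, rho = -0.84). Endothelial genes varied with the same YAP list (r = 0.92, permutation p = 0.00001, adjusted p = 0.0017) and against the E2F list (r = -0.86, permutation p = 0.00008, adjusted p = 0.0044), so this relation was not separated from the content of normal tissue. In the 10 of these tumors from mice 190 to 238, the coefficients of class I with interferon and of YAP with E2F were 0.89 (permutation p = 0.0007) and -0.94 (permutation p = 0.0004). In the 5 tumors of the other series they were 0.71 (exact permutation p = 0.133) and -0.94 (exact permutation p = 0.0417). Both series are parts of the same 15 tumors in which the pairs were picked, so these p-values are not independent support. Of the 15 tumors, the 2 farthest from the median of the first list of each pair (class I or YAP) were also left out. The coefficients were then 0.81 and -0.86.

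The RNAs Malat1 and Rpph1 stood at 237 and 160 FPKM in sgControl RPP tumor 1, against 3.77 to 34.5 and 0 to 5.39 FPKM in the other 15 tumors. In the same tumor the neutrophil list lay 2.49 above the other tumors on the log2 scale after median scaling (-0.641 to 0.854 for each of the 15), and the erythroid list 1.68 above (-1.22 to 1.02).

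Whether the group labels or the tumors' own differences gave the counts of passing genes and lists was tested by regrouping the tumors. Of 100 groupings of the 16 tumors, the labelled one included, 6 gave at least 1 gene past the threshold, with 254 in the most extreme of the others, and 87 gave at least 7 lists. The most lists in another grouping was 22, and the median was 11, so chance was not excluded as the source of either count.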
